A study of Mus musculus with 4 samples.

How the data were processed

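Gene expression was measured in mouse embryos that lack nucleoredoxin (the gene Nxn, whose product is a thioredoxin-related protein) and in wild-type embryos, at embryonic days 9.5 and 11.5 (E9.5 and E11.5). Per the labels, both genotypes were C57BL/6J, total RNA was amplified linearly from an oligo-dT primer that carries a T7 promoter, and each of 4 two-colour Agilent whole mouse genome arrays received Nxn-null RNA in 1 dye and wild-type RNA of the same stage in the other. Each stage had 2 arrays with the dyes exchanged: replicate 1 carried the Nxn-null RNA in Cy5 and replicate 2 carried it in Cy3. The labels do not say that the arrays of a stage came from separate RNA extracts, so the arrays of a stage were averaged and counted as 1 replicate. P-values therefore measure only the spread between these arrays or between the stages, which may be technical. The number of embryos behind each RNA is not given in the sources used here.

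The deposited scanner files hold, per the file headers, spot intensity in each channel on a linear scale with its local background, as written by Agilent Feature Extraction. The headers name version 9.1.3.1 and the submitters' processing notes name version 9.5.3.1. Per the file headers, the same files also hold a log10 ratio of the red over the green processed signal, which was used here only as an alternative. The deposited value table of the series was set against that log10 ratio over 40929 probes. Between 99.995% and 100% of its values were equal to it within 0.0001, once the sign was turned on the arrays with the Nxn-null RNA in Cy3. The table is therefore on the log10 scale, runs as Nxn-null over wild type and was not centred further beyond that tolerance. Its column medians were -0.0136 and 0.0408 for replicates 1 and 2 at E9.5, and -0.0347 and 0.0210 at E11.5.

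Mean spot intensities were corrected for the local median background by normexp with an offset of 50, and loess was applied within each array with control spots at weight 0, in limma 3.58.1 under R 4.3.3, with jsonlite 2.0.0 and version 1.17.8 of the data.table package. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. Spots of 1 probe were averaged and 293 probes with an outlier mark on at least 1 array were left out. Of 41174 gene probes, 24994 were kept because Feature Extraction called them well above background in at least 1 genotype on both arrays of a stage. The brightest probe stood for each gene, which left 17161 genes or transcripts for testing. Among these, 5711 had several probes, and in 2349 of them the probes differed in the sign of the mean ratio. Gene names were updated with a RefSeq gene table of assembly GRCm38.p6, which was used only for symbols and gene order. A total of 22951 probes matched it by accession, 6659 by current symbol and 3109 by an older symbol, and 8455 kept the name in the files. Of the tested genes, 14342 had a current symbol. No coordinates are given, because the files name no genome build.

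Every array carried 43379 spots outside the control types. The share of gene probes well above background was 69.2% in the Nxn-null and 57.8% in the wild-type channel of E9.5 replicate 1, and 51.4% and 65.6% in replicate 2. At E11.5 it was 63.7% and 48.1% in replicate 1, and 59.9% and 70.1% in replicate 2, so the Cy5 channel passed more often on each array. Between 0 and 7 spots per array were saturated. The number of arrays limits the precision of every value.

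Ratios are log2 of Nxn-null over wild type. The genotype effect shared by E9.5 and E11.5 was tested with limma on the 2 stage averages, which leaves 1 residual degree of freedom (prior degrees of freedom 2.87). Every SE given with n = 2 stages or n = 2 genotypes is the moderated SE of limma, which is drawn towards the spread of all genes. Where the 2 values lie far apart, it is smaller than the SE of those 2 values alone and understates their disagreement. Following the design text of the series, which takes genes with a mean fold change above 2 at both stages as a signature, genes at least 2-fold apart were counted at each stage and at both, with no test. A second limma fit on the 4 arrays, with a dye term, asked which ratios at a stage, or differences of the ratio between stages, lay beyond array spread. Array spread here is how far the difference between dye-swapped arrays at E9.5 departed from that at E11.5, on 1 residual degree of freedom. The part of that difference common to both stages is taken out as the dye effect and does not enter the error. That fit compares the RNAs hybridised, not genotypes. The stage effect shared by both genotypes was tested with limma on E11.5 over E9.5 differences of single channels after Aquantile normalization between arrays, with the 2 genotypes as replicates. Effects common to both channels of an array do not enter its error, so its p-values are too small. P-values were adjusted by the Benjamini-Hochberg method at 0.05. Where a gene was well above background on no array of a group, its fold is a bound: the mean of the brighter group over the dimmer group, each array of the latter set at the higher of its own signal and the lowest signal well above background there, per channel after loess and Aquantile.

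A total of 29 gene lists were fixed before the data were examined: Wnt targets, Wnt pathway components, thioredoxin and redox genes, glycolysis, hypoxia, heart muscle, skeletal muscle, bone and cartilage, neural crest and face, neuron, neural progenitor, somite and tailbud, limb, primitive red cell, definitive blood, macrophage, endothelium, liver, yolk sac, placenta, decidua and uterus, proliferation, p53 targets, interferon response, sex-linked, neighbours of Nxn, posterior Hox, extracellular matrix and ribosomal protein genes. They were tested with camera at a preset correlation of 0.01, and again with the correlation estimated. With the correlation estimated, camera has 1 residual degree of freedom here and can hardly call any list, so it neither upholds nor overturns a call. The preset correlation is an assumption that these arrays cannot check, so the camera p-values may be too small. The lists share few gene symbols: the limb and posterior Hox lists share 3 tested genes, and no other pair shares more than 1. Genes of 1 list can still be expressed in the tissue of another, as with liver and yolk sac. The tests, the alternatives and the rule for named genes were also fixed before the data were examined. The rule takes Nxn, 10 genes per direction for the shared effect, 5 per direction for each stage and for the stage effect, 3 per direction for the difference between stages, up to 4 members of each list, and all members of the sex-linked and Wnt target lists. Where fewer than 10 genes passed the test of the shared effect, the places were filled by size from genes 2-fold apart at both stages and then from genes of the same direction on all 4 arrays. The text names only part of the genes the rule takes, by symbol, and the tables hold their values.

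The fits were tested on simulated data over the 17161 genes, with 200 changed genes in each of 10 runs. For differences beyond array spread at E9.5, the fit recovered 100% of the genes changed by 1.5-, 2- and 4-fold, but 15.3% of its calls were false (10 to 74 false calls per run), above the nominal share. For the shared effect, with noise drawn from the fitted prior, it recovered 12.7% of the genes changed by 1.5-fold, 86.3% by 2-fold and 98.6% by 4-fold, with 6.68% of its calls false. With noise drawn from each gene's own SD it recovered 0% at each of these sizes. The alternatives were the Feature Extraction log ratio, the value table, an offset of 10, median centring in place of loess, no filter on dim probes, a filter on both channels of every array, the mean of all probes, moderation with trend and robust settings, the 4 arrays as separate measurements, no dye term, other fold rules, other scalings between arrays, and leaving out each array.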

Results

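The series compared Nxn-null with wild-type mouse embryos at E9.5 and E11.5, to ask which genes depend on nucleoredoxin, and the series title names the maintenance of Wnt/beta-catenin signalling. Each stage was measured on 2 arrays with exchanged dyes, so every ratio at a stage rests on n = 2 arrays and every shared ratio on n = 2 stages. The log2 ratios of the dye-swapped arrays correlated across genes at 0.48 for E9.5 and 0.26 for E11.5, and the averages of the stages at 0.16 (Spearman 0.20). Arrays of the same dye orientation correlated across the stages at 0.34 and 0.36, and arrays of opposite orientation at -0.08 and -0.16. Genes are not independent replicates, and these correlations only describe the arrays.

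Nxn itself was lower in the Nxn-null RNA on all 4 arrays. The log2 ratio of its brighter probe was -1.04 and -0.93 at E9.5 and -1.24 and -1.42 at E11.5, a mean of -1.16 ± 0.11 (SE, n = 2 stages) or 44.8% of the wild-type level. Its other probe had a mean of -0.98, or 50.6% of the wild-type level. Both stage ratios lay beyond the spread between arrays (limma adjusted p = 2.57e-08 at E9.5 and 4.22e-09 at E11.5), whereas the test over the stages gave an adjusted p of 0.387. The labels do not say whether either probe lies in the disrupted part of the gene, so a level of about this size does not show whether the transcript is lost.

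The known targets of Wnt/beta-catenin signalling showed no common shift. The median log2 ratio of the 33 tested members of this list (of 37 listed) was -0.05 at E9.5 and 0.04 at E11.5. Axin2, the feedback inhibitor used as a general readout of the pathway, had ratios of -0.05 ± 0.16 and 0.09 ± 0.09 (SD, n = 2 arrays). Lef1, a transcription factor of the pathway, had -0.09 ± 0.01 and 0.01 ± 0.05, Sp5 had -0.12 and 0.18, and Nkd1 had 0.02 and 0.24. At E9.5, 8 targets were lower beyond array spread, with the largest ratios for Cdx2, a regulator of posterior identity (-2.27 ± 0.13, 4.82-fold lower), Tbx6, a regulator of presomitic mesoderm (-2.11 ± 0.13, 4.30-fold lower), and T, the mesodermal factor brachyury (-0.77 ± 0.10). Cdx2 was well above background in 3 of the 4 channels at E9.5, so the size of its fold is uncertain. The 3 higher targets were Ephb2 (0.32), Apcdd1 (0.26) and Wif1 (0.24). At E11.5, Fgf8 (0.32 ± 0.13) and Nkd1 were higher and none lower beyond array spread, and Cdx2, Tbx6 and T stood at -0.16, 0.05 and 0.07.

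No Wnt target changed by limma over the stages, over all genes or adjusted over the list alone, and 1 of the 33 had an unadjusted p under 0.05. The list as a whole had a camera p of 0.727 (adjusted p = 0.761, and 0.923 with an estimated correlation). Its shared median of -0.0054 turned to 0.07 with median centring, which does not remove the dye trend, and lay at 0.0038 and 0.0019 with other choices of probes. Of the 59 tested components of the pathway, 6 were higher and 7 lower beyond array spread at E9.5, and 4 were higher and 2 lower at E11.5, with list medians of 0.04 and 0.03 (camera adjusted p = 0.258). Wnt3a, a ligand, had ratios of 0.55 ± 0.07 and 0.38 ± 0.07, and Sfrp1, a secreted antagonist, had 0.19 ± 0.24 and 0.68 ± 0.15. The receptor Fzd6 was at -0.05 ± 0.15 at E9.5 and -1.05 ± 0.19 at E11.5, and the coreceptor Lrp5 at -0.42 ± 0.01 and -0.22 ± 0.08.

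**Figure D1:**
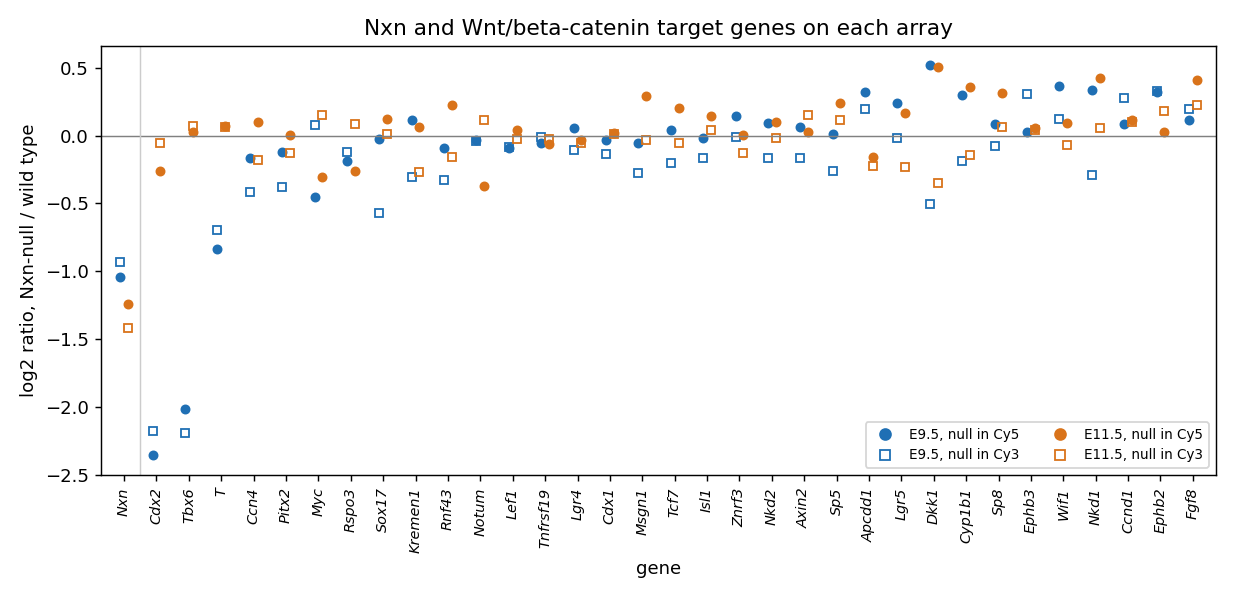
Log2 ratio of Nxn-null over wild type (y axis) for Nxn and the 33 tested Wnt targets, ordered by mean ratio (x axis), with 1 point per array, blue for E9.5 and orange for E11.5, filled where the Nxn-null RNA was in Cy5 and open where it was in Cy3. Nxn lies below 0 on all 4 arrays, and Cdx2, Tbx6 and T lie below 0 on both E9.5 arrays at means of -2.27, -2.11 and -0.77.

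Genes of primitive red cells were lower at both stages. Of 20 tested members, 19 were lower in the Nxn-null RNA on all 4 arrays, and the list median was -0.47 at E9.5 and -0.64 at E11.5. Hbb-y, an embryonic beta-like globin, had a mean ratio of -1.30 ± 0.10 (SE, n = 2 stages; 2.46-fold lower). Klf1, the erythroid transcription factor that activates globin genes, had -0.93 at E9.5 and -1.49 at E11.5, the embryonic globins Hbb-bh1 and Hba-x had -0.84 and -1.25, and -0.34 and -1.02, and the blood group protein Rhd had -0.68 and -0.83. The list fell by camera (adjusted p = 5.92e-22). It was not called by camera with an estimated correlation (adjusted p = 0.876), a setting that can hardly call any list here. By limma 17 members fell when adjusted over the list alone and 0 over all genes tested, with 17 at an unadjusted p under 0.05.

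Over all 17161 genes, no gene passed the limma test of the shared genotype effect, whose lowest adjusted p was 0.387. An unadjusted p under 0.05 was reached by 1248 genes where chance gives 858, and moderation with trend and robust settings also called 0 genes, with 0 at an unadjusted p under 0.05. With the 4 arrays taken as separate measurements, limma called 3529 genes, but those arrays may repeat the same RNA. Among the highest genes of the same direction on all 4 arrays, Cuedc1 had a mean of 1.51 ± 0.31 (SE, n = 2 stages), H4c9, a histone H4 gene, 1.24 ± 0.57 (2.36 at E9.5 and 0.11 at E11.5), Hddc3 1.15 ± 0.12, Crebzf, a bZIP transcription factor, 0.95 ± 0.06 and Zfp429 0.80 ± 0.16. Without E9.5 replicate 1, where its other probe stood for the gene, Cuedc1 had 0.96. Zfp874a, also among them, was not well above background in the wild-type E9.5 RNA. For Med1, a subunit of the Mediator complex (0.96 ± 0.21), Nosip (0.94 ± 0.06) and Gadd45gip1 (0.93 ± 0.23), another probe gave -0.06, 0.03 and -0.63. Fam199x (0.71 ± 0.08) was not well above background in either genotype at E11.5 and had 0.30 without E9.5 replicate 1 and -0.41 with the Feature Extraction log ratio.

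Among the lowest genes of the shared effect were Apob and Apoa1, apolipoproteins made by yolk sac and liver, at -2.00 ± 0.71 and -1.57 ± 0.67 (SE, n = 2 stages), Igfbp1, which binds insulin-like growth factors, at -1.99 ± 0.77, and Apoc2 at -1.74 ± 0.73. Spp2, Cfi, the complement factor I protease, and Pdzk1 followed at -1.70 ± 0.84, -1.34 ± 0.65 and -1.32 ± 0.66. The low mean of these 7 genes came mainly from E9.5, where Apob stood at -3.40 against -0.61 at E11.5; over the 4 arrays the Apob probes had means from -2.00 to -0.48. Snhg14, a host transcript of small nucleolar RNAs, had -1.36 ± 0.11, while another of its probes gave 0.02. Neither these genes nor the higher ones passed the test, at adjusted p-values of 0.387 or more by limma.

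At E9.5, 144 genes were at least 2-fold apart, 15 higher and 129 lower in the Nxn-null RNA. The lowest were S100g, a vitamin D-regulated calcium-binding protein, at -4.73 ± 0.45 (SD, n = 2 arrays; 26.6-fold lower), Cubn, the cubilin receptor of endocytic epithelia, at -4.25 ± 0.45 (19.1-fold), Igfbp1 at -3.50 ± 0.24 (11.3-fold), Myl2, the regulatory myosin light chain of the ventricle, at -3.43 ± 0.26 (10.8-fold), and Apob at -3.40 ± 0.56 (10.5-fold; -2.63 with the mean of all probes). The highest were Prl8a2, a prolactin-family gene of the decidua, which was not well above background in the wild-type RNA and was at least 5.59-fold higher, H4c9 at 2.36 ± 0.01, Prdm16, a transcriptional regulator, at 2.26 ± 0.02, Zfp874a, at least 2.55-fold higher, and Prl3d2, a placental lactogen, at 1.41. The 144 genes became 490 (92 higher, 398 lower) with the Feature Extraction log ratio, 95 (9 and 86) with both channels required above background, 276 (30 and 246) without E9.5 replicate 1 and 180 (65 and 115) without E9.5 replicate 2. The Feature Extraction log ratio put S100g, Cubn and Apob at -6.70, -4.95 and -4.43, and Prdm16 and Prl3d2 at 3.03 and 2.44.

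Yolk sac genes were lower at E9.5, with a list median of -1.41 and 16 of 18 members lower beyond array spread. Besides Cubn, they included its partner Amn (-3.07), the homeobox gene Rhox5 (-3.01) and the fibrinogen chain Fgg (-2.76). Of 22 liver genes, 14 were lower and 1 higher beyond array spread (median -0.65), among them the fetal serum protein Afp (-3.37) and the retinol carrier Rbp4 (-3.32). Afp, Rbp4 and the apolipoproteins are also made by yolk sac, so this list does not tell liver from yolk sac. The liver plasma proteins Alb and Ahsg went another way between the stages, with a lower ratio at E11.5 than at E9.5 (differences of -0.58 and -0.83). Of 25 heart muscle genes, 20 were lower and 0 higher (median -1.06), with the myosin heavy chain Myh7 at -2.43, the natriuretic peptide Nppa at -2.13 and the myosin light chain Myl3 at -1.84; a second probe of Myl3 stayed near 0 over the 4 arrays (-0.12). Of 12 posterior Hox genes, 11 were lower (median -0.57), with Hoxd13 at -1.37, Hoxc9 at -1.33 and Hoxa10 at -0.97, and Hoxc10 at least 2.43-fold lower.

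Neuronal genes shifted the other way at E9.5: 14 of 23 were higher and 0 lower beyond array spread (median 0.29), with the neurofilament Nefm at 0.54 ± 0.03 (SD, n = 2 arrays), the tubulin-binding stathmins Stmn2 and Stmn3 at 0.56 ± 0.05 and 0.57 ± 0.28, and the neuronal tubulin Tubb3 at 0.53 ± 0.09. In the neural progenitor list, Olig3, a dorsal patterning factor, stood at 0.50, and 7 members were higher and 1 lower (median 0.12). The neural crest and face list had 7 higher and 0 lower members (median 0.08), with the melanoblast enzyme Dct at 0.48. Among genes of tissues outside the embryo, the placental lactogen Prl3d1 was higher (1.06) and the imprinted growth regulator Phlda2 lower (-2.20), with a placenta list median of 0.13; the decidua and uterus list had a median of 0.05. Glycolysis and hypoxia genes had medians of -0.15 each, 8 lower members in each list and 0 and 1 higher, with the mitophagy receptor Bnip3 at -0.72 and the lactate transporter Slc16a3 at -0.54.

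Averaged over the stages, camera called 9 of the 29 lists. Besides primitive red cell genes these were yolk sac (adjusted p = 3.21e-05), posterior Hox (2.08e-04), heart muscle (3.22e-04), liver (0.00799) and extracellular matrix genes (0.0124) as lower, and neuron (9.92e-06), neural progenitor (0.0239) and neural crest and face genes (0.0360) as higher. None of the 9 was called with an estimated correlation (adjusted p = 0.876 for each), a setting that can hardly call any list here. The shift of the yolk sac, heart muscle, posterior Hox, liver and neural lists came from E9.5, where their medians lay away from 0, whereas at E11.5 they were -0.03, 0.10, -0.02, -0.02, 0.04 for neuron, -0.01 for neural progenitor and 0.03 for neural crest and face. The fit of single genes at E9.5 called 4009 of 17161 beyond array spread by limma (1581 higher and 2428 lower), against 459 with no dye term. The false share of 15.3% in simulated data came from runs with 200 changed genes and does not carry over to the count of 4009. The count was 466 and 356 without E9.5 replicates 1 and 2, and 493 and 449 without E11.5 replicates 1 and 2, in fits that lose the dye term.

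At E11.5, 35 genes were at least 2-fold apart, 9 higher and 26 lower. The largest ratio was that of Xist, the RNA of the inactive X chromosome, at 5.83 ± 0.34 (SD, n = 2 arrays). Its probe was not well above background in the wild-type E11.5 RNA and read at least 57.0-fold higher. Another Xist probe was well above background there, so this bound holds for the 1 probe and not for the gene. Over the 4 arrays the Xist probes had means from 0.44 to 2.70. At E9.5, Xist was well above background in both genotypes, and Eif2s3y, Ddx3y and Kdm5d in neither. The Y-linked genes Eif2s3y and Ddx3y were not well above background in the Nxn-null E11.5 RNA and were at least 8.69-fold and 5.79-fold lower there, Kdm5d at least 2.25-fold and Orly at least 3.08-fold lower, while the Y-linked Zfy1 stood at -0.01. Cuedc1 was at 2.11 ± 0.19, Ywhaz, a 14-3-3 adaptor protein, at 2.05 ± 0.00, and Med1 and Gadd45gip1 at 1.36 ± 0.01 and 1.36 ± 0.30. With the mean of all probes, Xist, Ywhaz, Med1 and Gadd45gip1 stood at 3.35, 1.36, 0.40 and 0.25. Cuedc1 stood at 1.40 by its other probe, which stood for the gene without E9.5 replicate 1, and at 3.14 with the Feature Extraction log ratio. Mxra7 stood at -1.68 ± 0.01, with another probe at -0.03 over the 4 arrays, and Npsr1, the neuropeptide S receptor, at -1.50 ± 0.06.

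Without the sex-linked list, 31 of the 35 genes were left, among them Orly, which the list does not hold. The 35 became 129 (68 higher, 61 lower) with the Feature Extraction log ratio, 66 (34 higher, 32 lower) with an offset of 10, and 137 without E11.5 replicate 2. Primitive red cell genes were the largest group at E11.5, with 19 of 20 members lower beyond array spread. Extracellular matrix genes had 8 lower and 0 higher members among 27 (median -0.13), and 6 lower and 1 higher at E9.5 (median 0.00). The collagens Col14a1 and Col1a1 stood at -0.26 and -0.42 (-0.88 and -0.46 at E9.5) and the matrix proteins Fn1 and Dcn at -0.37 and -0.24 (-0.21 and -0.27 at E9.5). Heart muscle genes had 5 higher and 1 lower member, and glycolysis genes 3 higher and 0 lower (median 0.12). Of 14 interferon-response genes, Bst2, which tethers virions, and Oas1a, an oligoadenylate synthetase, were higher (0.87 and 0.85) and Stat2 lower (-0.23). Beyond array spread limma called 1457 genes (574 higher, 883 lower), against 130 without E9.5 replicate 1, 183 without E9.5 replicate 2, 16 without E11.5 replicate 1 and 35 without E11.5 replicate 2.

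The medians of the remaining lists at E9.5 and E11.5 were 0.02 and -0.01 for thioredoxin and redox genes, 0.03 and 0.00 for skeletal muscle, 0.11 and -0.02 for bone and cartilage, -0.05 and 0.03 for somite and tailbud, -0.06 and 0.05 for limb, and -0.09 and -0.07 for definitive blood. Of the 26 bone and cartilage genes, 9 were higher and 4 lower beyond array spread at E9.5, and 3 higher and 6 lower at E11.5. Macrophage genes had 0.01 and 0.05, endothelium -0.09 and -0.02, proliferation 0.02 and 0.02, p53 targets -0.03 and 0.02, interferon response -0.09 and 0.04, ribosomal protein genes 0.01 and -0.01, and neighbours of Nxn 0.02 and 0.01. Camera adjusted p-values for these lists, the Wnt, glycolysis, hypoxia, placenta, decidua and sex-linked lists lay between 0.194 and 0.913. In 4 lists the median, mean and test of the shared effect differed in sign: skeletal muscle, somite and tailbud, macrophage and neighbours of Nxn. Adjusted over the list alone, limma called Hba-a1 (-0.60 and -1.13 at E9.5 and E11.5) and Car2 (-0.40 and -0.79) of the definitive blood list and Glod4 (-0.78 and -0.71), a neighbour of Nxn; over all genes none of the 3 was called. Among the redox genes the peroxiredoxin Prdx3 stood at -0.24 and -0.33.

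**Figure D2:**
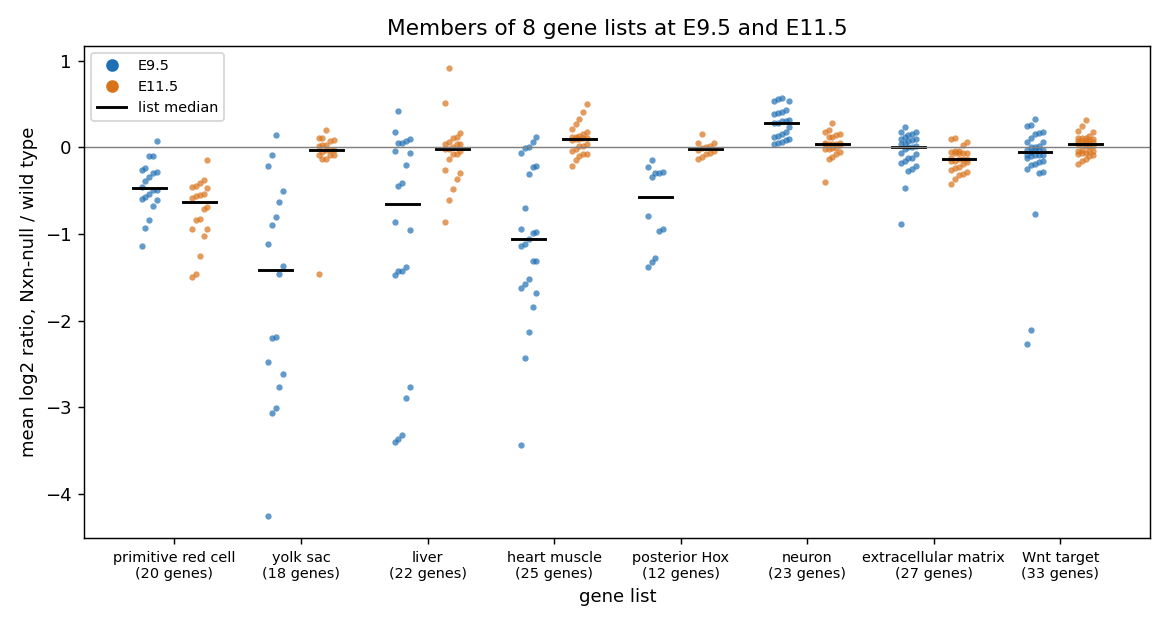
Mean log2 ratio of Nxn-null over wild type (y axis) for each tested member of 8 gene lists (x axis), with 1 point per gene, blue for E9.5 and orange for E11.5, and a bar at the list median. The primitive red cell medians are -0.47 and -0.64, whereas the yolk sac, heart muscle and posterior Hox medians go from -1.41, -1.06 and -0.57 at E9.5 to -0.03, 0.10 and -0.02 at E11.5.

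At both stages, 5 genes were at least 2-fold apart in the same direction, where independent stages would give 0.0085 higher and 0.212 lower. Hbb-y (-1.14 ± 0.36 and -1.46 ± 0.22, SD, n = 2 arrays) and Snhg14 (-1.53 and -1.19) were lower, as were 2 transcripts known only by database identifiers. The gene 2810410L24Rik, named here after its values were seen, was higher (1.24 and 1.14). None of the 5 was 2-fold apart on each array alone. With the Feature Extraction log ratio 19 genes passed, and without E9.5 replicate 2 or without E11.5 replicate 1 only 3 did.

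**Figure D3:**
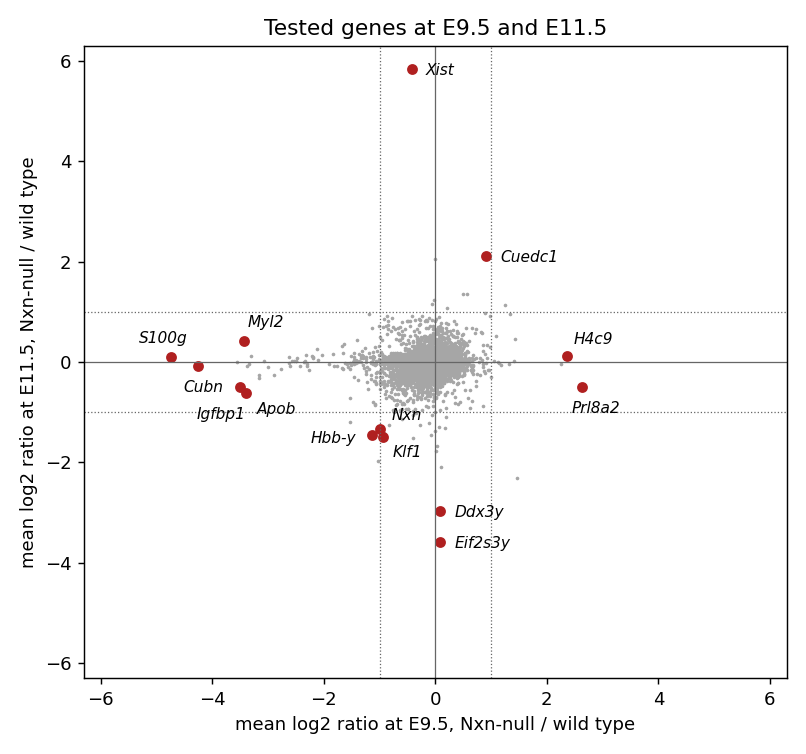
Mean log2 ratio of Nxn-null over wild type at E9.5 (x axis) and at E11.5 (y axis), with 1 grey point for each of 17161 tested genes, named genes in red and dotted lines at 2-fold. Cubn and S100g lie far to the left at -4.25 and -4.73, Xist far up at 5.83, and Nxn and Hbb-y below and left of 0 on both axes.

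The difference of the ratio between the stages was largest in the fit for Xist, S100g and Cubn (4.17 higher at E11.5 than at E9.5), and, in the other direction, for Eif2s3y, Prl8a2 and Ddx3y. Except for Cubn, the probes of these genes were not well above background in at least 1 RNA, so their order and sizes are not known. By limma, 2176 genes differed between the stages beyond array spread, 1354 with the higher ratio at E11.5 and 822 with the lower. Camera called 17 of the 29 lists, and none with an estimated correlation (adjusted p between 0.461 and 0.482), which can hardly call any list here. Members of the largest list shifts were Cubn, Amn, Rhox5 and Fgg for yolk sac, Myl2, Nppa, Myh7 and Nppb for heart muscle, and Rbp4, Afp, Apob and Apoa1 for liver. With all 4 arrays and no dye term the count of genes was 149. Leaving out 1 array also lowered the count of 2176, in fits that lose the dye term.

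Between E9.5 and E11.5, 586 genes changed at least 2-fold in both genotypes together, 452 higher and 134 lower at E11.5. S100a9, a calcium-binding protein of myeloid cells, rose by 4.43 ± 0.17 (SE, n = 2 genotypes; limma adjusted p = 0.0054), the liver plasma proteins Alb and Ahsg by 4.06 ± 0.16 and 3.60 ± 0.22, Hic1, a transcriptional repressor, by 3.28 ± 0.11 and Cstdc6 by 3.20 ± 0.07. Prtg, an immunoglobulin-family receptor of the early neural tube, fell by 3.02 ± 0.06, Lin28a, which blocks let-7 processing, by 2.97 ± 0.12, Wfikkn1 by 2.55 ± 0.06 and the galectin Lgals2 by 2.43 ± 0.63. Kdm4a, a histone demethylase, fell by 2.77 ± 0.08, while its other probe gave 0.25. At E9.5, S100a9 and Cstdc6 were well above background in 3 of the 4 channels and Ahsg in 2 of 4, and at E11.5 Lin28a, Wfikkn1 and Lgals2 in 3 of 4. The fall of Lgals2 was unequal in the genotypes (-3.65 in wild type and -1.20 in Nxn-null RNA). The log2 stage differences of the genotypes correlated at 0.82 across genes, and effects common to both channels of an array are left out of the error of these tests.

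Primitive red cell genes rose between the stages (median 1.07, 10 of 20 members past the test and 2-fold), with Rhd at 2.27 and the anion exchanger Slc4a1 at 1.52. Neuronal genes rose by a median of 0.78 (10 members), with the microtubule protein Mapt at 2.45, macrophage genes by 0.94 (8 members), with the complement component C1qc at 2.03, and skeletal muscle genes by 0.72 (8 members), with the embryonic myosin Myh3 at 2.29. Camera also called extracellular matrix (0.65), definitive blood (0.50), bone and cartilage (0.38) and liver genes (0.26) as higher, and yolk sac (-0.81), placenta (-0.71) and proliferation genes (-0.30) as lower. None of these 11 lists was called with an estimated correlation (adjusted p between 0.893 and 0.897), a setting that can hardly call any list here. The fall of the yolk sac genes was unequal in the genotypes and larger in wild-type RNA, since their ratio rose by a median of 1.41 between the stages. Scaling each channel to its 75th percentile moved the median of all genes by 0.21 and the count to 915 (814 higher and 101 lower).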

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

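All explanations in this part were put to tests chosen only after the result was seen.

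The ratio of Nxn-null over wild type differed between the stages for 84 of the 110 genes named in the text, by limma on the 4 arrays with a dye term (adjusted p of 0.0388 or less). The test compares the RNAs hybridised. For Xist, S100g, Prl8a2, Prl3d2, Zfp874a, Eif2s3y, Ddx3y, Orly, Kdm5d, Tbx4, Oas1a and Hoxc10 the probe was not well above background in at least 1 RNA, so the values given for them in this part are those of the fit and not measured sizes. The log2 ratio at E11.5 minus that at E9.5 was -0.34 for Nxn. It was 4.83 for S100g, and for genes of the yolk sac list 4.17 for Cubn, 3.1 for Amn, 2.92 for Rhox5 and 2.63 for Fgg. In heart and skeletal muscle it was 3.84 for Myl2, 2.39 for Nppa, 2.36 for Myh7, 2.00 for Nppb, 1.99 for Myl3, 1.51 for Myh8, 1.06 for Myl1 and 1.04 for Acta1, and -0.47 for Myh3. For secreted and metabolic proteins of liver and yolk sac it was 3.43 for Rbp4, 3.30 for Spp2, 3.29 for Afp, 3.01 for Igfbp1, 2.85 for Apoc2, 2.79 for Apob, 2.64 for Apoa1, 2.59 for Pdzk1, 2.53 for Cfi and 2.45 for Lgals2, but -0.58 for Alb and -0.83 for Ahsg. In posterior and limb patterning it was 2.16 for Tbx6, 2.11 for Cdx2, 1.53 for Hoxd13, 1.34 for Hoxc9, 1.16 for Hoxc10, 1.14 for Pitx1, 0.94 for Hoxa10, 0.83 for T and 0.77 for Tbx4.

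Among placental and decidual genes it was 2.32 for Phlda2, -1.04 for Prl3d1, -1.39 for Prl3d2 and -3.14 for Prl8a2. Neural genes had negative differences: -0.38 for Nefm, -0.48 for Tubb3, -0.50 for Stmn2, -0.50 for Olig3, -0.53 for Stmn3, -0.71 for Mapt and, in melanoblasts, -0.45 for Dct. So had red cell genes, with -0.39 for Car2, -0.41 for Hbb-bh1, -0.45 for Slc4a1, -0.53 for Hba-a1, -0.56 for Klf1 and -0.68 for Hba-x. In the Wnt lists it was 0.49 for Sfrp1, 0.30 for Sp5, -0.45 for Apcdd1 and -0.995 for Fzd6. Genes in none of these groups with a higher ratio at E11.5 were Ywhaz (2.05), Cuedc1 (1.20), Oas1a (1.15), Bst2 (0.98), Gadd45gip1 (0.86), Bnip3 (0.83), Slc16a3 (0.82), Med1 (0.80), Col14a1 (0.62), Gpx3 (0.50), Lin28a (0.42) and Snhg14 (0.34). Those with a lower ratio were Hic1 (-0.35), Hddc3 (-0.39), Txnip (-0.41), Zfp429 (-0.58), S100a9 (-0.62), Zfp874a (-0.96), Npsr1 (-1.10), Mxra7 (-1.71), H4c9 (-2.24) and Prdm16 (-2.30).

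Of the 29 lists, 17 differed between the stages by camera, none with an estimated correlation (adjusted p between 0.461 and 0.482), which can hardly call any list here. The median difference was 1.41 for yolk sac, 1.23 for heart muscle, 0.99 for liver, 0.60 for posterior Hox, 0.29 for glycolysis, 0.19 for hypoxia, 0.12 for limb, 0.10 for somite and tailbud and 0.10 for Wnt target genes. It was -1.36 for sex-linked, -0.30 for neuron, -0.28 for primitive red cell, -0.17 for bone and cartilage, -0.13 for neural progenitor, -0.12 for extracellular matrix, -0.080 for neural crest and face and -0.059 for decidua and uterus genes.

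Yolk sac, heart muscle and posterior Hox genes were low at E9.5 and near 0 at E11.5. Less yolk sac in the Nxn-null E9.5 RNA stays open for the yolk sac genes, since the 16 of 18 that were lower are what raised it, but does not account for the 31 of 37 heart muscle and posterior Hox genes that were lower too. Slower development of the whole embryo alone would raise the yolk sac genes, whose median stage effect was -0.81. It would also lower neuronal genes, which rose with stage but had a median of 0.29 at E9.5. The neuronal values argue against it as the only cause, since the rise of 0.78 exceeded the difference between the genotypes in that change (-0.30). The yolk sac value decides little, because the wild-type E9.5 RNA enters both the stage effect and the ratio. It also averages unequal falls: the ratio rose by a median of 1.41 between the stages, so wild-type RNA fell further. Ratios are relative, however, so less of another tissue in the Nxn-null RNA would raise the neuronal share. The stage effect compares arrays and depends on the tissue kept at each stage. Slower development together with such a loss therefore stays open. Less posterior tissue stays open for the Hox genes. Their ratio at E9.5 ran against paralogue number (Spearman -0.62 over 35 Hox genes, medians of 0.04 for groups 1 to 5 and -0.57 for groups 9 to 13). This largely repeats the low posterior Hox genes that raised it, and genes of a Hox cluster are not independent. Outside the clusters, the Wnt targets Cdx2, Tbx6 and T and the hindlimb factor Pitx1 were also low at E9.5. Less posterior tissue could lower them too, so their fall does not by itself show less Wnt signalling. They were picked after their values were seen. The somite and tailbud list had 4 of 16 members lower and 0 higher beyond array spread, with a median of -0.05. What parts of the conceptus were dissected, how many embryos were pooled, and a delay of heart or trunk alone stay open, as does an effect of Nxn.

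Xist was higher and Y-linked genes were lower at E11.5, with fitted differences between the stages of 6.26 for Xist, -3.68 for Eif2s3y, -3.05 for Ddx3y, -1.79 for Orly and -1.36 for Kdm5d. Unequal shares of male and female embryos in the E11.5 RNAs were tested by the highest ratio among the 4 Y-linked members of the list, which was -0.0085 for Zfy1, but this excludes nothing, because the Zfy1 probe lies near background (well above it on 1 of 2 arrays in the Nxn-null and 2 of 2 in the wild-type RNA at E9.5, and on 2 of 2 and 1 of 2 at E11.5). The ratios of the other 3 members, the highest at -1.36, raised this explanation and cannot test it. At E11.5 each of these 3 was well above background on 2 of 2 arrays in the wild-type RNA and on 0 of 2 in the Nxn-null RNA. The Xist probe passed on 0 of 2 and 2 of 2, although another Xist probe passed in the wild-type RNA. In the wild-type RNA at E9.5 these 3 passed on 0 of 2 arrays and the Xist probe on 2 of 2. The wild-type RNAs of the stages thus differed in the same genes, which the Nxn genotype cannot account for. This argues against an effect of Nxn as the only cause for these genes, whereas a difference in sex or stage could give it. An added genotype effect at E11.5 cannot be told apart from a difference in sex between the RNAs. An effect of the genotype on Xist at both stages is opposed by its ratio of -0.43 at E9.5, and an exchange of the E11.5 RNAs by the Nxn ratio of -1.33 ± 0.12 (SD, n = 2 arrays), of the same direction as at E9.5. Whether other genes that differ at E11.5 follow the sex of the embryos was not tested.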

How the results depend on the processing

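Added after the data were seen were the settings of the primitive red cell, yolk sac, heart muscle and posterior Hox lists. So were the counts without the sex-linked list (31 at E11.5, Orly still among them) or without yolk sac, liver and heart genes (112 at E9.5). No paired analysis was possible because the replicate numbers mark only the dye orientation, which the dye term already takes out, and the stage averages have none. Nxn and the direction of the primitive red cell, yolk sac, heart muscle and posterior Hox lists kept their sign under every setting run. The shared effect gave 0 genes by limma under each setting except with the 4 arrays as separate measurements, which gave 3529. Where no cause is named, the cause was not tested.

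With the Feature Extraction log ratio, 490, 129 and 19 genes were 2-fold apart at E9.5, E11.5 and both stages; these held 139 of the 144 and all 35 genes counted at a stage. Beyond array spread it gave 1531 at E9.5, 168 at E11.5 (76 higher, 92 lower) and 579 between the stages. The value table gave 489, 129, 19, 1402, 44 and 466. Both gave medians of -2.55 for yolk sac and -1.01 for posterior Hox genes at E9.5, and both turned Fam199x to -0.41. An offset of 10, which shrinks dim ratios less by construction, gave 66 genes at E11.5 and a yolk sac median of -1.84. Median centring, which leaves the dye trend in, gave 658 at E9.5, 210 at E11.5 (116 higher, 94 lower) and 382 between the stages (306 higher, 76 lower), and a Wnt target median of 0.073. With both channels above background, which leaves fewer genes, 95 and 3 genes were 2-fold apart at E9.5 and at both stages, and the medians were 0.0038 for Wnt targets, -1.65 for yolk sac and -0.87 for posterior Hox genes. The mean of all probes gave 3 genes at both stages and a Wnt target median of 0.0019. Without the dye term, which leaves the dye effect in the error, limma gave 459, 34 and 149. A 1.5-fold rule gave 496, 186 (68 higher, 118 lower) and 37 genes, and 2-fold on each array alone gave 0 at both stages. Camera with an estimated correlation, which can hardly call any list here, did not call primitive red cell genes at an unchanged median of -0.57 (p = 0.178). Scaling each channel to its 75th percentile gave 915 genes for the stage effect.

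Leaving out each array in turn gave 144 to 276 genes 2-fold apart at E9.5 (276 without E9.5 replicate 1), 31 to 137 at E11.5 (137 without E11.5 replicate 2; 92 higher, 45 lower) and 3 to 6 at both stages (3 without E9.5 replicate 2 and without E11.5 replicate 1). Beyond array spread, with no dye term left in these fits and the lone array of a stage assumed to vary like the others, E9.5 gave 356 to 493 genes (466 and 356 without E9.5 replicates 1 and 2, 493 and 449 without E11.5 replicates 1 and 2). E11.5 gave 16 to 183 (130, 183, 16 and 35 in the same order), and the stage difference 112 to 239 (239, 232, 112 and 146). The Wnt target median ran from -0.041 to 0.037 and the yolk sac median from -1.56 to -1.27. For 40 ratios of 33 single genes, 20 of the shared effect and 20 at a stage, the values at a stage stayed within 1 SD in 114 of 180 cases and moved further in 66; 37 moved by over 1.5-fold. Of 200 values of the shared effect, 21 moved by over 1.5-fold, 20 passed the threshold and 2 changed sign; that the others stayed on their side says little, because the test called no gene. Signal over background limits genes that pass in 1 genotype alone: their fold at that stage is a bound, and other values printed for them are those of the fit and not measured sizes.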

Other observations

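All tests on chromosomes in this part were chosen only after the result was seen.

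The thioredoxin and redox list, the family of nucleoredoxin, had 2 members higher and 3 lower beyond array spread at E9.5 and 0 higher and 2 lower at E11.5, among 35 tested. Gpx3, an extracellular glutathione peroxidase, stood at -0.32 and 0.18, and Txnip, the thioredoxin-binding arrestin, at 0.25 and -0.16, at E9.5 and E11.5. The skeletal muscle list had a median of 0.03 at E9.5, with 6 of 20 members lower and 2 higher beyond array spread; the lower ones included Myh8 at -1.54, Myl1 at -1.24 and Acta1 at -1.08. Of the 16 limb genes, 5 were lower and 1 higher at E9.5, with the hindlimb factors Pitx1 and Tbx4 at -1.14 and -0.72, the latter not well above background in the Nxn-null RNA and at least 1.64-fold lower there.

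Genes apart in the same direction at both stages crowded on chromosome 11, which carries Nxn, and on chromosome 7. Without Nxn and the blood lists, 77 genes were at least 0.4 (log2) apart at each stage and of 1 direction on all 4 arrays; 21 lay on chromosome 11 (odds ratio 4.16, Fisher's exact test, adjusted p = 1.68e-05 over the chromosomes) and 16 on chromosome 7 (odds ratio 3.15, adjusted p = 0.00231). A limit of 0.3 gave odds ratios of 2.33 and 2.54, and 3.24 for chromosome 8, and a limit of 0.5 gave 4.22 and 3.66. Red cell genes on chromosome 11 cannot account for the 21, which exclude them, and DNA of another strain kept around Nxn (the labels give C57BL/6J for both genotypes) stays open for chromosome 11, whose excess raised it, but would leave chromosome 7 at no excess. Of the 21 genes, 17 lay more than 100 tested genes from Nxn, with 4 nearer where 3.51 were due by chance (Fisher's exact p = 0.767), which argues against DNA kept close to Nxn for most of them and leaves open longer or separate stretches of another strain, or a response to Nxn.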
